A study of Mus musculus with 16 samples.

How the data were processed

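The deposited data cover 16 samples of mouse splenic B cells, 4 KO and 4 Flox by RNA-seq and 4 KO and 4 Flox by Ago2 HITS-CLIP. The authors' RNA-seq table gives 43432 gene rows with the values of 8 libraries, whose columns name the Flox libraries WT. Its values are a signal that the authors made by dividing gene counts by 1 size factor per library and rounding to 1 decimal. The deposited table also holds variance-stabilized values on a log2 scale, and the authors' log2 fold change, fold change ratio, p-values with their FDR, and the gene GC content in percent, per the file headers. The labels name cutadapt, Bowtie2, SAMtools, STAR, DESeq2 and DESeq without versions or roles, and mm9 as the build. The gene positions and the CLIP positions are those of GRCm38: regions reach beyond chromosome ends of mm9, and 87.6% of CLIP regions lie in a gene of the table on the same strand, against 7.69% on the opposite strand and 24.5% after a shift of 1000000 nt. Gene names come from the table, with 42673 of its rows carrying a symbol and 42462 IDs found in the reference name table.

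The deposited dCLIP output gives, per 5-nt bin, a difference score and a hidden state (other than positions), per the file headers, and the deposited summary gives a score per region. It also has 4 columns of per-condition tags and mutations, whose genotype the headers do not name. These 4 columns could not be matched to a group and are not used, although they had been looked at before this was settled. Because the conditions are not named, no direction by genotype was assigned to CLIP. The 13147668 bins were joined into 962700 regions, and all of them (100%) matched the summary. Regions on unplaced sequence, or below position 3000000 of a chromosome other than M and Y, were left out (616). A region's difference is the mean of its bins, and a region was given to each gene whose span it overlapped on the same strand. The reference holds no sequence and no exon positions, so the seed match comparisons planned for 3′ UTRs and CLIP regions were not run, and exons, introns and UTRs were not told apart; distance to the gene's annotated 3′ end is given instead.

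The RNA-seq values stepped in whole multiples of 1 read, and at least 99.96% of values in each library came out whole within 0.1 read. Library depth was 28485074, 22947689, 26397279 and 39236132 reads in KO 1 to 4 and 39616596, 33463898, 25421025 and 28581592 in Flox 1 to 4. The plan made before the data were examined was edgeR's test for counts, with limma-trend for normalized values without recoverable counts. Since the deposited unit is normalized, limma-trend (limma 3.58.1) on log2 of the value plus 1 was made the main test although whole reads were recovered, and edgeR (4.0.16) on those reads became an added alternative, which called 10 genes. Genes with a mean of at least 10 over the 8 libraries were kept, 13091 in all, and 20488 rows were 0 throughout. The threshold was a Benjamini-Hochberg adjusted p of 0.05, two-sided. The p-values measure the spread between these samples only.

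Gene lists were fixed before the data were examined: 29 lists covering targets from the literature, class switching, antibody genes, B cell identity and fate, signalling, cell cycle, cell death, chromatin, the miRNA machinery, markers of other cell types, mitochondrial mRNA, sex genes and the locus. The 25 lists with at least 3 tested genes were compared by camera with a correlation of 0.01, by camera with an estimated correlation, and by fry. Named genes were those past the threshold with a mean of at least 5 CPM and no overlap between groups, up to 12 per direction by adjusted p, without predicted genes, pseudogenes and variable segments. Added to these were 14 genes named from the start, some of which are not reported here, and up to 4 genes per list by p. For CLIP the rule asked for the regions with the largest tag difference toward each genotype. Without usable tags or named conditions, the 10 regions of each sign with the highest score were taken instead, and up to 4 regions per named gene with a score of at least 5 and a mean difference of at least 0.25 were added after the values were seen.

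Alternatives set beforehand for RNA-seq were TMM scaling, no filter, a stricter filter (1 CPM in each group and 50 reads in all), DESeq2 (1.42.0), limma-voom, the replicate number as a block, leaving out each library in turn, leaving out immunoglobulin genes and a fold of at least 1.5. For CLIP a width of at least 20 nt was run, while limits of 10 or 50 tags and of 2-fold were not, as they need the tag columns. Chosen after seeing the data were edgeR, a pseudocount of 10, a correction for gene span and GC content by natural splines with 4 degrees of freedom per library, DESeq2 with the same trend as offsets, library quality weights, leaving out KO 1 and KO 3 together, a term for replicate numbers 1 and 2 against 3 and 4, limits of 5 on the CLIP score and of 0.25 on the mean difference, and the gene-level comparison of CLIP with RNA-seq. The last matched genes within 25 strata of expression and gene span and used 100000 permutations.

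The steps were tested on simulated data. On 13091 simulated genes limma-trend recovered 40% of genes changed 1.5-fold, 65% of those changed 2-fold and 82.5% of those changed 4-fold, with 8 false calls among 12891 unchanged genes. Camera gave a p under the threshold for 40 of 40 lists of 20 genes raised 1.3-fold and for 1 of 40 unchanged lists. The simulated genes were drawn independently of each other. These counts therefore do not cover lists whose genes vary together, such as the miRNA machinery (estimated correlation 0.293) and mitochondrial mRNA (0.869). The permutation of CLIP gene classes returned a mean of 0.0898 for a planted shift of 0.1, past the threshold in 20 of 20 draws, and 1 of 20 draws with no shift passed. The work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and bedtools 2.31.1.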

Results

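RNA abundance and Ago2-bound RNA were measured in splenic B cells of mice lacking miR-221 and miR-222 (KO) and of Flox mice, which carry the floxed locus. The cells had been grown for 4 days with an antibody to CD40 (500 ng/ml), IL-4 (25 ng/ml) and IL-21 (10 ng/ml), signals that drive B cells to divide and to switch their antibody class. The series holds 8 RNA-seq libraries and 8 Ago2 HITS-CLIP libraries, 4 per genotype and assay. HITS-CLIP sequences the RNA fragments that stay crosslinked to a protein after its immunoprecipitation, here Ago2, the protein that carries miRNAs to their target RNAs. RNA-seq depth was 22947689 to 39236132 reads in the KO libraries and 25421025 to 39616596 in the Flox libraries. The deposited CLIP output pools the replicates of each genotype, so the CLIP values given here carry no error between mice. The deposited CLIP output compares a pair of conditions without saying which is KO, so no CLIP difference is given a direction by genotype here.

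The first question was what the deposited RNA-seq shows at the deleted locus. The annotated spans of Mir221 and Mir222 were too sparsely read to check the labels. Mir221 (ENSMUSG00000065422, GRCm38 chromosome X, 19146294 to 19146388) had 0 reads in each KO library and 0, 0, 3 and 1 reads in Flox libraries 1 to 4. Mir222 (ENSMUSG00000065471, chromosome X, 19146893 to 19146971) had 0 reads in all 8 libraries, which allows up to 3 reads in each. The gene model Gm14636, a processed transcript on the same strand at 19156981 to 19167241, separated the genotypes. It had 288, 220, 238 and 248 reads in KO libraries 1 to 4 and 1, 2, 1 and 3 reads in the Flox libraries.

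The next comparison asked which genes differ between KO and Flox B cells. Of 13091 genes tested, 9 passed the threshold on adjusted p, 7 higher and 2 lower in KO (limma-trend on log2 normalized counts, Benjamini-Hochberg adjustment). The rule for naming genes took 4 of them. Gdpd3, a lysophospholipase D (chromosome 7, 126766334 to 126775649), rose from 24.8 ± 6.81 to 1256 ± 374 normalized counts (SD, n = 4 per group), a log2 fold change of 5.60 (SE 0.25) with a limma adjusted p of 1.78e-06. Ppp1r16b, a regulatory subunit of protein phosphatase 1 (chromosome 2, 158665398 to 158766334), rose from 4895 ± 155 to 10465 ± 1359, a log2 fold change of 1.09 (SE 0.09). Tnfrsf26, a receptor of the tumour necrosis factor family (chromosome 7, 143607659 to 143628722), fell from 1540 ± 167 to 395 ± 66.3, a log2 fold change of -1.97 (SE 0.13). The tetraspanin Tspan32 (chromosome 7, 143005046 to 143019644) fell from 1556 ± 92.1 to 878 ± 70.6, a log2 fold change of -0.83 (SE 0.09). In each of these 4 genes every KO library lay beyond every Flox library, as the naming rule required.

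**Figure D1:**
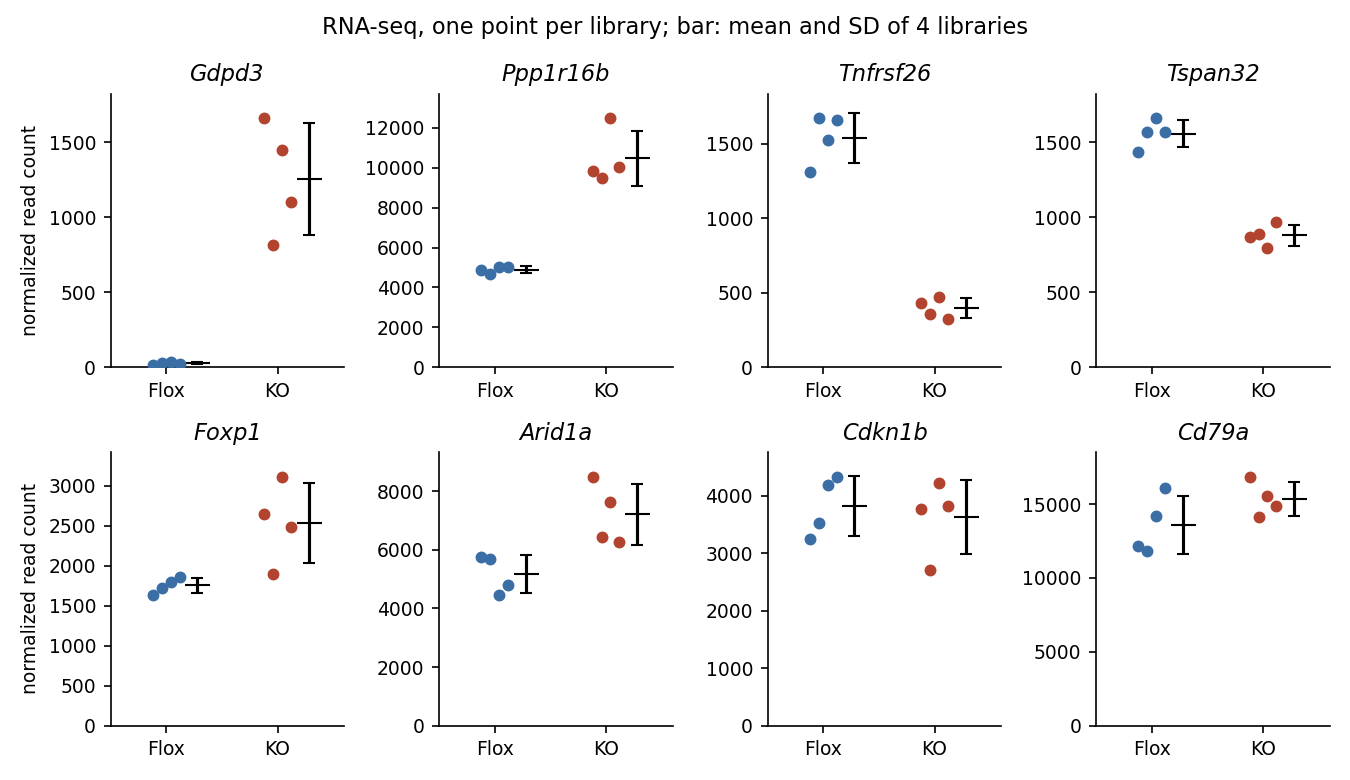
Normalized read counts (vertical axes, from 0) of 8 genes in the 4 Flox and 4 KO libraries, 1 point per library, with the mean and SD of each group. Gdpd3 and Ppp1r16b lie higher in every KO library and Tnfrsf26 and Tspan32 lower; Foxp1 and Arid1a lie higher in every KO library by less than 2-fold, and Cdkn1b and Cd79a overlap between the groups.

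The other 5 genes that passed fell outside the naming rule and were picked after their values were seen. Gm14636 was at 264 ± 51.8 normalized counts in KO and at a mean of 1.70 in Flox. Gm9855, a pseudogene row, was at 156 ± 52.3 in KO and had 0 reads in each Flox library. Its parent gene Tdg, thymine DNA glycosylase, was at 234 ± 47.9 in KO and 395 ± 25.0 in Flox, and the sum of the Tdg and Gm9855 rows was 390 ± 62.8 and 395 ± 25.0, so reads shared between these rows leave both values uncertain. Dnmt3c, a DNA methyltransferase gene of rodents, was at 30.6 ± 10.2 in KO with 0 reads in each Flox library. Lyplal1, a lysophospholipase-like gene, was at 106 ± 19.7 in KO and 23.4 ± 3.81 in Flox, and its call was lost without KO 1 and KO 3 together. Mid1, a microtubule-associated ubiquitin ligase, was at 29.4 ± 9.88 and 3.73 ± 0.29, and its call was lost in 15 of 22 settings, among them without any 1 of KO 2, KO 3, KO 4 or Flox 1 to 4.

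With these 9 included, 1981 genes had an unadjusted p under the threshold, where 655 would be expected by chance, and in 1043 genes (7.97%, against 2.86% by chance) the groups did not overlap. The count of 1981 depended on single libraries, from 1003 without Flox 3 to 2767 without KO 2. Without KO 1 and KO 3 together it was 820, against 655 expected. DESeq2 on the reads recovered from the table called 195 genes, and the authors' deposited table calls 191, 132 higher and 59 lower in KO, among 12118 genes with an adjusted p. All 191 had an unadjusted limma p under the threshold and the same direction, and 9 passed after adjustment. Without KO 2 the limma count was 17 and without KO 4 it was 14.

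Foxp1 and Arid1a, a transcription factor of B cells and a subunit of the BAF chromatin remodelling complex, are the genes that the study followed as targets, picked from data that include these samples. Neither passed in limma. Foxp1 (chromosome 6, 98925338 to 99522721) was at 2538 ± 501 normalized counts in KO and 1755 ± 95.6 in Flox (n = 4 each), a log2 fold change of 0.51 (SE 0.13, limma adjusted p = 0.239), and it passed without KO 2. Arid1a (chromosome 4, 133679008 to 133756769) was at 7208 ± 1051 and 5176 ± 643, a log2 fold change of 0.48 (SE 0.12, limma adjusted p = 0.238). Both rose when p was adjusted over the list of these followed targets alone. They were higher in all 4 KO libraries than in any Flox library, and the authors' deposited table gives adjusted p of 0.0253 and 0.0313. With a correction for gene span and GC content, added after the values were seen, DESeq2 gave Foxp1 a log2 fold change of 0.33 (SE 0.11, adjusted p = 0.0745) and Arid1a 0.39 (adjusted p = 0.0328).

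Targets of these miRNAs that were named in the literature did not pass as a set with all libraries. Of 29 tested genes in that list, 16 had a positive and 13 a negative log2 fold change, with a median of 0.03, a mean of -0.04 and a downward camera test (adjusted p = 0.779, camera with a preset correlation of 0.01). Without KO 1 and KO 3, fry called the list downward (adjusted p = 0.0265). By a p adjusted over the list alone 3 fell: Ddit4, an inhibitor of mTOR signalling (-0.46), the immediate-early gene Fos (-0.76) and the CDK inhibitor Cdkn1c (-0.92). Cdkn1c was read at only 33.15 ± 6.83 normalized counts in KO and 63.6 ± 13.3 in Flox. It lies on chromosome 7 (143458339 to 143461050), between Tspan32 and Tnfrsf26, so its fall may not be separate from theirs. The CDK inhibitor Cdkn1b had a log2 fold change of -0.08 (SE 0.14) in limma, and its sign turned without KO 2 and with the span and GC corrections. Bbc3, which encodes the death activator Puma, was at -0.35 (SE 0.12), Kit, a receptor tyrosine kinase read at 21.9 and 10.5 normalized counts, at 0.75 (SE 0.50; 0.28 without KO 1), and Bcl2l11, which encodes the death activator Bim, at 0.03 (SE 0.09). The sign of Bcl2l11 turned without Flox 1.

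Gene lists fixed beforehand were then compared. The 29 lists hold 452 tested genes, of which 0 passed over all genes in limma, 99 had an unadjusted p under the threshold, and 0 passed in edgeR and 10 in DESeq2. Of the 25 lists large enough for a set test, camera with its preset correlation called 7. With a correlation estimated from the data it called 0, with adjusted p from 0.491 to 0.508 for these 7 lists.

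In the BAF complex list, the only list of chromatin remodelling genes, 20 of 24 genes had a positive log2 fold change (median 0.18, camera adjusted p = 1.36e-04; adjusted p = 0.508 with an estimated correlation and 0.111 with fry). Within the list, 6 rose by a p adjusted over it alone, among them Bicra (0.74), Arid1a (0.48), Smarcc2 (0.45) and Arid1b (0.42), all core or accessory subunits. Arid1a, a BAF subunit, is also a gene that the study followed, picked from data that include these samples, so its part in the count is not independent evidence. In the miRNA machinery list 13 of 17 were positive, with a median of 0.25 (camera adjusted p = 0.00367; adjusted p = 0.508 with an estimated correlation and 0.222 with fry). Of these 6 rose by a p adjusted over the list alone, such as Ago2 (0.38) and Tnrc6a (0.43), which encodes a GW182 protein, while Lin28a, a repressor of let-7 maturation, fell (-0.48). Many genes of both lists are long, and fold changes rose with gene span in these libraries (median log2 fold change of -0.12 in the shortest 20% of protein-coding genes with a mean of at least 50 and 0.13 in the longest 20%). With the span and GC correction both lists stayed past the threshold with camera's preset correlation, at adjusted p of 3.29e-04 and 0.00655 (0.512 for both with an estimated correlation). Arid1b went from 0.42 to 0.26 with this correction, and its DESeq2 call (adjusted p = 0.0459) was lost with span and GC offsets (adjusted p = 0.109). The DESeq2 calls of Bicra, Arid1a and Smarcc2 held with these offsets. Some KO libraries stood apart from the rest. On the first principal component of the tested genes (33.5% of the variance) KO 1, KO 2 and KO 3 lay at -38.0, -15.4 and -35.6, KO 4 at 7.48 and the Flox libraries at 14.5 to 26.5, and KO 3 had the lowest library quality weight (0.310, against up to 3.69 in Flox 3). Gene rows with at least 1 read numbered 17201 ± 1130 in KO and 18459 ± 319 in Flox (exact permutation p = 0.114). Without KO 1 and KO 3 both lists passed with the preset correlation (adjusted p of 0.00202 and 0.0204; 0.504 and 0.577 with an estimated one).

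B cell identity genes had a median of 0.12, 22 of 33 positive (camera adjusted p = 0.0133; adjusted p = 0.508 with an estimated correlation), a call lost without KO 1 (adjusted p = 0.0725), Flox 1 (0.0656), Flox 2 (0.0667), or KO 1 and KO 3 together (0.0795). Adjusted over the list alone 1 rose, Pax5, the B lineage transcription factor (0.57), and Pou2f2 (0.31) and Cd22 (0.26), an octamer-binding factor and an inhibitory receptor, were also higher on average. In the PI3K and FOXO list 18 of 26 genes were positive (median 0.12, camera adjusted p = 0.0428; adjusted p = 0.508 with an estimated correlation). Adjusted over the list alone 0 passed in limma, with 9 at an unadjusted p under the threshold and 1 called by DESeq2, Ddit4, which fell against the direction of the list (-0.46). Its members included Sesn3 at 0.36 and Irs2 at 0.58, and its call was lost without KO 1 (adjusted p = 0.0611), KO 3 (0.176), KO 4 (0.0822), Flox 1 (0.130), or KO 1 and KO 3 together (0.261), with the stricter filter (0.0697), with edgeR (0.0672) and with the span and GC correction (0.217). In this list DESeq2 with span and GC offsets called Irs2 (0.64, adjusted p = 0.0284) and not Ddit4 (-0.28, adjusted p = 0.118). Cd79a, a chain of the B cell receptor complex, was at 0.19 (SE 0.11), and at 0.12 without Flox 2.

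Glycolysis and hypoxia genes lay lower, 18 of 22 negative with a median of -0.15 (camera adjusted p = 0.0153; adjusted p = 0.508 with an estimated correlation), a call lost without KO 2 (adjusted p = 0.243) or Flox 4 (0.0574). The same list differed between replicate numbers 1-2 and 3-4 with a smaller camera adjusted p (1.66e-04, median 0.12). None passed over the list alone in limma, where 3 had an unadjusted p under the threshold and DESeq2 called 0; Pgam1 and Eno1, both glycolytic enzymes, had log2 fold changes of -0.88 and -0.60 (Eno1 at -0.38 without KO 3). Mitochondrial mRNAs lay higher, 6 of 7 positive with a median of 0.50 (camera adjusted p = 0.0140; adjusted p = 0.508 with an estimated correlation), among them mt-Co1 at 0.57 and mt-Cytb at 0.50 (0.34 and 0.32 without KO 3), with 0 past the list alone in limma, 2 at an unadjusted p under the threshold and 0 called by DESeq2. They took 2.93, 2.07, 4.05 and 1.65% of reads in KO libraries 1 to 4 and 1.78 ± 0.10% in Flox (exact permutation p = 0.171), and the list's call was lost without KO 3 (adjusted p = 0.189).

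**Figure D2:**
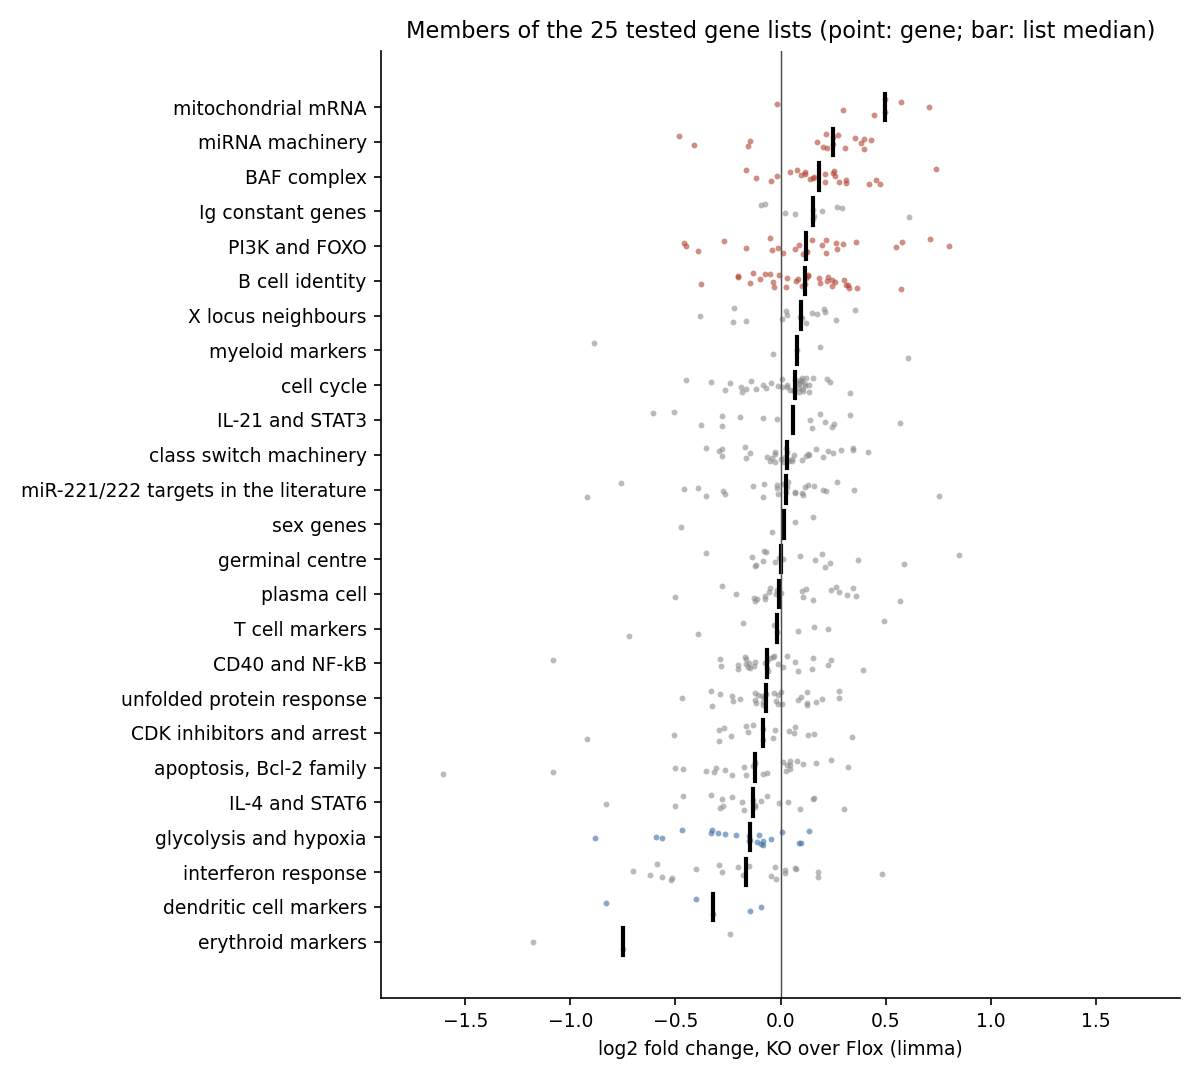
Log2 fold change of KO over Flox (horizontal axis, limma) of each member of the 25 tested gene lists, 1 point per gene, with the list median as a bar. Red and blue lists passed camera with a preset correlation, upward and downward; the medians run from -0.75 (erythroid markers) to 0.50 (mitochondrial mRNA).

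Lists for class switching, the process that the cytokines set off, did not pass in the main comparison, and their calls depended on the setting. In the class switch machinery list 22 of 35 genes were positive (median 0.03, camera adjusted p = 0.178), 0 passed over the list alone in limma, 4 had an unadjusted p under the threshold and DESeq2 called 0. The list passed without KO 1 and KO 3 (adjusted p = 0.0457; adjusted p = 0.504 with an estimated correlation). Paxip1 and Rnf168, both acting in the repair of switch region breaks, were at 0.34 and 0.29. The antibody constant genes had a median of 0.16 (9 of 11 positive, camera adjusted p = 0.178), with Ighg1 at 0.16 (SE 0.10), Ighe at 0.16 (SE 0.13; 0.25 without KO 1, 0.08 without KO 3, 0.09 without KO 4 and 0.10 without Flox 2), Ighm at 0.15 (SE 0.30) and Ighd at 0.61 (SE 0.27; 0.34 without KO 1). This list passed, upward, without KO 2 (adjusted p = 0.0483; 0.458 with an estimated correlation) and with the span and GC correction (median 0.27, adjusted p = 0.0350; 0.512 with an estimated correlation). The sign of Ighm turned without KO 3 (-0.03), and with any other 1 library left out Ighm ran from 0.00 (without KO 4) to 0.40 (without KO 2). Immunoglobulin genes took 3.04 ± 0.78% of reads in KO and 2.67 ± 0.50% in Flox (exact permutation p = 0.457).

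Lists of B cell activation and fate did not pass in camera with all libraries. Camera adjusted p was 0.163 for germinal centre genes (median 0.00, 9 of 18 positive; the receptor Ccr6 at 0.85, higher in Flox 1 than in the other Flox libraries), 0.415 for plasma cell genes (median -0.01 against an upward test; Mzb1 at -0.50 and Prdm1 at 0.57, or -0.32 and 0.34 without KO 3), 0.289 for CD40 and NF-kB genes (median -0.06; Traf3 at 0.23), 0.0827 for IL-4 and STAT6 genes (median -0.13; Gfi1 at -0.50) and 0.776 for IL-21 and STAT3 genes (median 0.06, mean -0.02; Stat3 at 0.24 and Socs3 at -0.38). It was 0.332 for the unfolded protein response (median -0.07; Hspa5 at -0.33 and Ddit3 at -0.47) and 0.153 for interferon response genes (median -0.17; Irf7 at 0.48). Cell cycle genes had a median of 0.07 (camera adjusted p = 0.395; Mki67 at 0.33, or 0.19 without KO 3, and Cdk1 at -0.26), and CDK inhibitors and arrest genes one of -0.08 (adjusted p = 0.163; 0.0333, downward, with fry after TMM scaling; Cdkn2d at -0.51). In the apoptosis list, with a median of -0.12 (camera adjusted p = 0.138), 2 of 27 genes fell when adjusted over the list alone, the death activator Pmaip1 (-0.50) and the survival factor Bcl2a1d (-1.08). Bcl2a1d also fell in the CD40 and NF-kB list by that measure. Some of these lists passed, downward, with libraries left out: IL-4 and STAT6 genes without KO 1 (adjusted p = 0.0293) or Flox 3 (0.0489), and interferon response genes without KO 1 (0.0469). With an estimated correlation their adjusted p was 0.373 for both without KO 1 and 0.496 without Flox 3. Without KO 1 and KO 3 together, these 2 lists (0.0457 and 0.0204), CDK inhibitors and arrest genes (0.0408) and the apoptosis list (0.0266) passed, all downward, with an adjusted p of 0.336 for each with an estimated correlation.

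Markers of other cells that the spleen could bring were few. Dendritic cell markers lay lower, with 5 of 5 negative and a median of -0.32 (camera adjusted p = 0.0133, or 0.491 with an estimated correlation, and fry adjusted p = 0.0173). Adjusted over the list alone 3 fell, the receptor Flt3 (-0.32, at 2288 ± 271 normalized counts in KO and 2853 ± 176 in Flox), Bst2 (-0.40) and Batf3 (-0.83; -0.51 without KO 3), and both Bst2 and Batf3 stand in B cell activation lists as well. T cell markers had a median of -0.02 (9 genes, camera adjusted p = 0.767, an upward test; Lck at 0.22), myeloid markers 0.08 (5 genes, mean -0.01, adjusted p = 0.816) and erythroid markers -0.75 (3 genes, adjusted p = 0.138; 0.0106 with fry without KO 2). NK and stromal markers had 2 tested genes each and no set test; adjusted over the list alone Prf1 (0.66), which encodes perforin, and Pecam1 (0.36), an adhesion receptor, rose. Of the sex genes Eif2s3y fell by the same measure (-0.47) and Ddx3y was at -0.04 (0.01 without KO 1 or without Flox 1), with a camera adjusted p of 0.531. Neighbours of the deleted locus on chromosome X had a median of 0.10 (12 of 16 positive, camera adjusted p = 0.178), called upward by fry without Flox 1 (adjusted p = 0.0141). The 2 deleted miRNA genes had no tested member.

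The CLIP comparison asked where Ago2 was bound more in one condition. The difference scores, states and region scores given here are the authors'. After 616 regions outside placed sequence were left out, the authors' deposited table held 962084 regions, of which dCLIP gave 318336 a negative difference (state 0), 89332 a positive difference (state 2) and 554416 no difference (state 1). Negative differences thus made up 78.1% of the 407668 regions with a difference. They were the weaker ones: their scores had a median of 2.30 and reached down to 0.60, against a median of 6.70 and a lowest score of 2.90 for positive differences. At a score of at least 5, a limit chosen after the values were seen, 48769 negative and 67457 positive regions were left. These values pool the 4 CLIP libraries of each genotype, so no test between replicates stands behind these counts. Mir221 and Mir222 had 0 regions.

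Many of the regions with the highest scores lay in abundant noncoding RNA. In the authors' deposited table the top 2 negative regions were in Gm42418, in the ribosomal RNA locus (chromosome 17, 39847440 to 39848174 and 39846360 to 39847419, scores 789.8 and 758.6). A region in Cmss1 (677.4) and one outside genes (chromosome 16, 18533195 to 18533329, score 670.5) came next, then mt-Rnr2 and mt-Rnr1 (665.0 and 652.7). Of the top 10 positive regions, 9 lay in the same locus, in Gm26917 and Gm42418, the first at 39843465 to 39843509 (score 711.0). That locus thus held strong regions of both signs.

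Tnfrsf26 stood out among genes by its difference. In the authors' deposited table its region at chromosome 7, 143607865 to 143608174, on the minus strand and 206 nt from the annotated 3′ end, had a mean difference of 0.797, the highest of all positive regions. Its region at 143608340 to 143608909 had 0.609. Over all its bins Tnfrsf26 had a mean difference of 0.302, rank 1 of the 6178 genes with at least 200 bins, whose median was -0.0427. Its RNA also differed between the genotypes, at 395 ± 66.3 normalized counts in KO and 1540 ± 167 in Flox. The difference scores were not corrected for RNA abundance here, so changed binding and changed abundance cannot be told apart. Of the genes that rose most in KO RNA-seq, Gdpd3 had 4 regions, all negative (mean -0.304), and Gm14636 had 4, of which 3 were negative (mean -0.236), but all of these scored under 5. Ppp1r16b had 918 regions, 258 negative and 124 positive, but 24 and 59 with a score of at least 5 and a mean difference of at least 0.25. Its region at chromosome 2, 158764685 to 158764784, had a mean difference of 0.605 and that at 158763695 to 158763769 one of -0.400. Tspan32, which fell, had 10 negative and 2 positive regions of 33 (mean -0.0170). Of other genes that rose, Lyplal1 had 1 region, a negative one, Dnmt3c had 1 without a difference, and Mid1 had 19 negative and 2 positive of 49.

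The followed targets held regions of both signs. Foxp1 had 1637 regions in the authors' deposited table, 568 negative and 107 positive, but 16 and 53 with a score of at least 5 and a mean difference of at least 0.25. The one with the highest score of these, at chromosome 6, 99064245 to 99064319, had a mean difference of 0.270. The one at chromosome 6, 98926295 to 98926344, within 957 nt of its 3′ end, had a mean difference of 0.278, and the one at 98935350 to 98935429 had -0.351 (score 14.3). Arid1a had 655 regions, 209 negative and 78 positive, or 18 and 43 within these limits. At chromosome 4, 133679010 to 133679199, at its 3′ end, the mean difference was 0.330 (score 36.5), and at 133679585 to 133679614 it was -0.251 (score 45.4). Over all bins the means were -0.0528 for Foxp1 and -0.0418 for Arid1a.

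Other genes named from the start differed in sign. Cdkn1b had 20 positive and 15 negative regions of 78 (15 and 6 within the same limits) in the authors' deposited table, a mean difference of 0.0495 over all bins (rank 25 of 6178) and its strongest region at chromosome 6, 134925300 to 134925364 (0.276, score 142.1). The top 4 regions of Bcl2l11 were all positive, the first at chromosome 2, 128161245 to 128161429 (0.339, score 132.6), and so were those of Ighg1 (0.259 to 0.378) and Ighe (0.268 to 0.434). Those of Ighm were all negative (-0.290 to -0.359). Bbc3 had 4 positive and 15 negative regions of 42 (2 and 0 within the limits above), and Cd79a had 1 and 12 of 29 (0 and 2 within the limits). Kit had 1 region, a negative one. No genome sequence was at hand, so matches to the seed of these miRNAs could not be looked for in any of these regions.

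**Figure D3:**
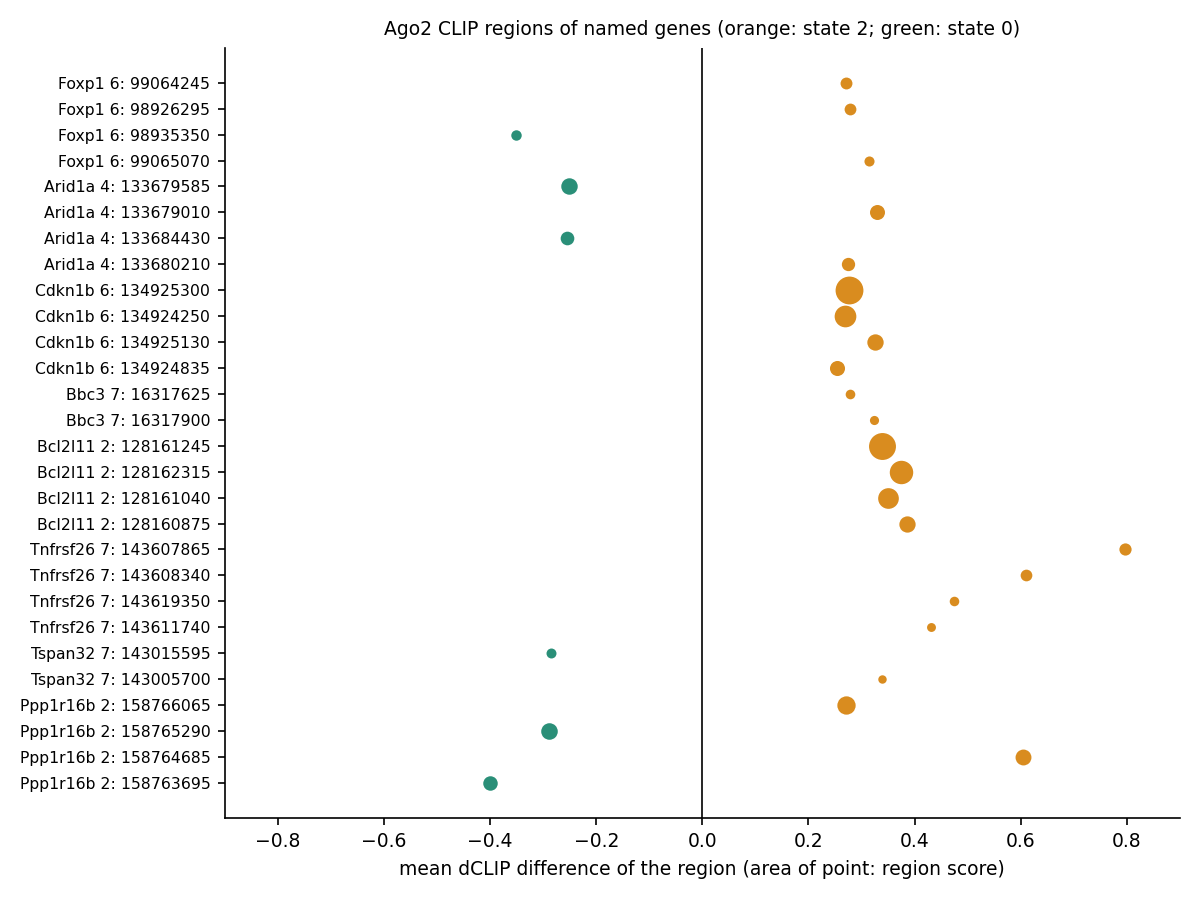
Mean dCLIP difference (horizontal axis, no unit) of named Ago2 CLIP regions in the authors' deposited table, each given by gene, chromosome and start in GRCm38, up to 4 regions per gene by score. The area of a point grows with the score. Tnfrsf26 regions lie from 0.432 to 0.797, and Foxp1, Arid1a, Tspan32 and Ppp1r16b have regions on both sides of 0.

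The last comparison set both assays together. It asked whether genes with an Ago2 region of a score of at least 5 and a mean difference of at least 0.25 also differed in RNA abundance, and it was added after the values were seen. For 1135 genes with such a negative region and no positive one, the median log2 fold change of KO over Flox lay 0.02 above that expected for 3940 genes with regions but no such difference, matched on expression and gene span (permutation p = 0.0300 over 100000 draws across genes, two-sided, adjusted p = 0.0600). For 1933 genes with a positive region and no negative one the shift was 0.00 (permutation p = 0.627, adjusted p = 0.627), and it was -0.02 and past the threshold without KO 3. Neither set passed after adjustment. As the CLIP differences were not corrected for RNA abundance, a shift could also come from abundance itself. Genes are not independent replicates, and camera, which treats them as correlated, gave adjusted p of 0.601 with its preset correlation and 0.434 with an estimated one for the negative set, and 0.668 and 0.434 for the positive set.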

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

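Chosen after the results were seen were the tests of shared Tdg reads, of the span and GC trend and of single libraries, and the counts of splits for the RNA-seq genes with limma and for the CLIP genes; the count of near neighbours and the counts of splits for DESeq2 and the gene lists were set before their results were seen.

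In 9 groups of 4 libraries 1 library stood far from the others, where 152 groups were looked at and chance gives about 7.6. The gap between that library and its nearest neighbour, as a share of the group's range, was 0.852 for Kit in KO 1 (49.7 normalized counts against 10.4 to 16.2), 0.835 for Sesn3 in KO 2 (779.8 against 897.4 to 920.6), 0.855 for Flt3 in KO 4 (2691 against 2107 to 2192), 0.835 for Mki67 in KO 3 (33157 against 21647 to 23541) and 0.917 for Trpm5 in KO 2 (11.7 against 34.9 to 37.0). In Flox 1 it was 0.918 for mt-Co1 (198495 against 216164 to 217733), 0.961 for Ccr6 (318.6 against 179.5 to 184.9) and 0.851 for Traf3 (1691 against 1521 to 1546), and in Flox 3 it was 0.872 for Tnfrsf22 (299.9 against 385.4 to 397.9).

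Other splits of the 8 libraries into 4 and 4 test whether chance can be excluded. For the number of RNA-seq genes it cannot: the real split gave 9 genes with limma, 2 of the 35 splits gave as many, and the highest other split gave 13, while each remaining split gave 0. This count does not speak on single genes, such as Gdpd3 with a limma adjusted p of 1.78e-06 or Gm14636 with 220 to 288 reads in KO libraries and 1 to 3 in Flox libraries, which lie far beyond the spread within groups. With DESeq2 the real split gave 195 genes, 3 of the 35 splits gave as many, and the highest other gave 331, so for that longer list chance cannot be excluded either. For the gene lists the real split called 7, 5 of the 35 splits called as many, and the highest other called 8, so chance cannot be excluded. For the shift of genes with a negative CLIP difference, 0.0276 as a mean within strata, 6 of the 35 splits were as large and the highest other was 0.0384, so chance cannot be excluded. The limma split with 13 genes set replicates 1 and 2 of both genotypes against 3 and 4, and the same split gave 239 genes with DESeq2. The split with 331 genes in DESeq2 kept KO 1, KO 2 and KO 3 together with Flox 1, and one with 8 lists kept KO 1, KO 3 and KO 4 with Flox 4. The split by replicate number is balanced in genotype, so its counts hold a difference by replicate number and no mean genotype difference. It was the only other split to reach the limma count of the real one. The split with 331 genes and that with 8 lists are not balanced and carry part of any genotype difference. The counts of these splits therefore set no clean level for chance.

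Several of the strongest RNA-seq genes lie close together. Tspan32, Trpm5, Tnfrsf26, Tnfrsf22 and Dhcr7, with log2 fold changes of -0.83, 2.76, -1.97, -0.82 and 0.53, start between 143.005 and 143.823 Mb of chromosome 7, and Gm14230, Tgif2 and Ppp1r16b between 156.833 and 158.665 Mb of chromosome 2. Cdkn1c, which fell in the list of literature targets (-0.92), lies in the same part of chromosome 7, at 143458339 to 143461050. Linked segments that differ between the mouse lines could put some of the 50 genes with the smallest p next to each other. Of these 50, 10 had another within 2 Mb. The other 34 splits gave a median of 10 and a highest value of 28, and random draws a median of 6. As many lay near each other in 2227 of 10000 random draws. The other splits are no clean reference, since they hold near genes of their own, 25 in the split with 13 limma genes. The count therefore cannot decide for or against linkage as a source of these genes. For Gm9855, shared reads were tested: the summed rows of Tdg and Gm9855 differed by -0.0302 on the log2 scale (SE 0.12, exact permutation p = 0.857). Reads moving from Tdg to its pseudogene row may thus account for the Gm9855 call and for the lower Tdg values, which did not pass in limma. Why reads would reach the Gm9855 row in KO libraries only (109.1 to 225.5 normalized counts, 0 in each Flox library) was not tested. Sequence differences between the mouse lines, at Tdg or at a locus such as distal chromosome 7, and an effect of the deletion itself stay open and were not tested.

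Fold changes rose with gene span, from a median log2 value of -0.12 in the shortest 20% of protein-coding genes with a mean of at least 50 normalized counts (0.374 to 8.63 kb) to 0.13 in the longest 20% (64.1 to 1690 kb), or from -0.05 to 0.08 without KO 3. Of 111 such genes that the authors call higher, 70 lie in the longest 20%, and of 51 they call lower, 5 do. A span and GC trend as the whole source of the authors' calls is argued against, since 78.5% of them (150 of 191) passed in DESeq2 with span and GC offsets. Differences between single libraries fit the trend: the rank correlation of a library's values with span ranged over 0.664 within 1 genotype, while the genotype means differed by 0.362 (0.129 and -0.232, exact permutation p = 0.0857). For Foxp1 the log2 fold change went from 0.53 (SE 0.14) to 0.33 with offsets, which lies between the bounds set for and against the trend, so the trend and a response to the genotype cannot be told apart there.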

How the results depend on the processing

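The alternatives with edgeR, a pseudocount of 10, span and GC terms, library weights, replicate numbers 1 and 2 against 3 and 4, KO 1 and KO 3 left out together, and limits on the CLIP score and difference were chosen after seeing the data, as were all settings of the comparison between CLIP and RNA-seq. The number of genes changed, 9 in limma, was 3 with the stricter filter, which tests fewer genes and leaves out 6 of the 9 for their low Flox level, Gdpd3 among them, 195 with DESeq2, 245 with DESeq2 and span and GC offsets, 14 with edgeR and the replicate block, and 16 with library weights, and it ran from 8 to 17 when single libraries were left out, 17 without KO 2 and 14 without KO 4. The cause was not tested for the settings other than the filter. With the replicate number as a block it was 11. Correlations of same-number libraries were -0.09, -0.06, -0.05 and 0.00, so no pairing by number was seen. They do not exclude a difference shared by several numbers, such as 1 and 2 against 3 and 4. The number of lists called, 7, was 0 with an estimated correlation and 1 with fry (dendritic cell markers), and ran from 5 to 8 when single libraries were left out. Without KO 1 and KO 3 the mitochondrial list turned downward (adjusted p = 0.679).

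Of 69 named genes, 43 kept direction and side of the threshold in each setting that gave a value, and 20 passed in at least 1 setting without passing in limma, 16 of them with DESeq2. Cdkn1b turned to 0.00948 with the span and GC correction, alone or with the replicate block, and 0.0263 with DESeq2 and offsets; leaving out single libraries gave -0.161 to 0.0522, positive without KO 2. Over single libraries left out, Bcl2l11 ran from -0.0308 (without Flox 1) to 0.0654, Ighm from -0.0277 (without KO 3) to 0.399 and Ddx3y from -0.0958 to 0.0107, positive without KO 1 or Flox 1. Ddx3y also turned to 0.0379 without KO 1 and KO 3.

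CLIP regions with a difference, 407668, numbered 116226 with a score of at least 5, 162118 with a mean difference of at least 0.25 and 78170 with both. Negative ones, 318336, numbered 48769, 110133 and 31609 in these settings, and positive ones, 89332, numbered 51985 with the difference limit and 46561 with both. Each of these limits removes regions by construction. The shift of genes with a negative region, 0.0198, passed the threshold at 0.0221 with the stricter filter, 0.0204 with limma-voom, 0.0283 with edgeR, 0.0208 with edgeR and the block, 0.0206 with the span and GC correction, alone or with the block, 0.0191 with DESeq2 and offsets, 0.0150 without KO 1 and KO 3 and 0.0279 with a difference of at least 0.3. It did not pass, at 0.0125 without immunoglobulin genes (adjusted p = 0.374), 0.0132 with DESeq2 (0.397), 0.0166 without a filter (0.237), 0.0159 with library weights (0.124), 0.0164 with a score of at least 10 (0.136), 0.0113 with regions near 3′ ends (0.208) and in the remaining settings. It ran from 0.0142 to 0.0294 when single libraries were left out and passed without any 1 KO library or Flox 1. The shift of genes with a positive region, 0.00379, ran from -0.0189 (without KO 3) to 0.0118 over single libraries left out, turned to -9.51e-04 with DESeq2 and offsets, -0.00447 with library weights and -0.0188 without KO 1 and KO 3. It passed downward without KO 3 (adjusted p = 2.8e-04) and without KO 1 and KO 3 (4e-05), and upward at 0.0160 with a score of at least 10. The cause was not tested. Limits of 10 or 50 tags and of 2-fold were not run, as the tag columns name no genotype. The seed match alternatives were not run, for want of a genome sequence, and neither were exon or UTR limits.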

Other observations

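A split by replicate number gave more genes than the genotype did. It was picked out because it gave the most limma calls of the 34 other splits, so its genes and p-values restate that count and do not test it. Between replicates 3 and 4 and replicates 1 and 2, both genotypes together, 13 genes passed in limma, all higher in 3 and 4. They include the antibody joining chain gene Jchain (13118 against 7023 mean normalized counts, log2 difference 0.90, limma adjusted p = 0.0176), the antibody variable segments Ighv1-82, Ighv1-26, Ighv9-1 and Ighv1-53, and the serpin gene Serpinb1a (log2 difference 1.36). The plasma cell list was higher in 3 and 4 with a median of 0.17 (24 genes, camera adjusted p = 6.44e-06; adjusted p = 0.0330 with an estimated correlation). With the preset correlation, glycolysis and hypoxia genes (adjusted p = 1.66e-04), antibody constant genes (0.00397) and the unfolded protein response (0.0235) were also higher and cell cycle genes lower (0.0149), and none of these 4 lists passed with an estimated correlation (adjusted p of 0.479 to 0.746). With this split of replicate numbers as a term, 9 genes differed between KO and Flox, 8 of them shared with the 9 above.

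Over all CLIP regions, positive ones lay near 3′ ends more often than others. Of 77386 positive regions in 1 protein-coding gene, 24.3% lay within 3000 nt of the gene's 3′ end, against 14.3% of 249682 negative ones and 14.7% of 467892 without a difference. With a score of at least 5 and a mean difference of at least 0.25 the shares were 29.2% and 32.5%, so the order turned under these joint limits. Under that limit on the difference, the positive protein-coding regions with the highest scores in the authors' deposited table were in Ctnnb1 (score 227.5, 233 nt from the 3′ end), Marcks (191.8), Zfp36 (180.7), Zfp36l1 (171.9) and Nfib (163.2), with Pmaip1 at 158.0. Negative ones included regions in Lars2 (616.4), Camk1d (573.7) and Cdk8 (509.8).

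Across 6071 genes with at least 200 bins, the mean CLIP difference and the RNA-seq log2 fold change had a Spearman rho of -0.0595 and a Pearson r of -0.0933 (permutation p = 1e-05, the smallest that the permutations can give). After the span and GC correction rho was -0.0661 and r -0.0997. This is a weak relation across genes, which are not independent replicates, and it was looked at after other relations between the assays had been seen.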
